A study of Mus musculus with 32 samples.

How the data were processed

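RNA from 32 mouse samples was measured on one-colour Agilent microarrays, 1 array per sample. Per the labels, total RNA was extracted with TRIzol, 200 ng was amplified and Cy3-labelled with the Low Input Quick Amp kit, and the strain was C57Bl/6. Per the file headers, the deposited scanner files give for each spot an intensity on a linear scale, background-subtracted and spatially detrended within the array by Agilent Feature Extraction 10.7.3.1, and not normalized between arrays. The deposited files also give raw median intensities of each spot and its local background, and flags for outlying, saturated and dim spots. The deposited series table holds the same intensity values (relative difference 0 on all 44397 spots of each array), so an analysis of that table was not run separately.

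The samples fell into 8 groups of 4 arrays. In culture these were control and knockdown arrays of a Pparg experiment, and control and knockdown arrays of a Gyk experiment. From mice they were Pparg control and knockout arrays at room temperature, and Pparg control and knockout arrays in the cold. Gyk is the study's name for glycerol kinase, which the gene table calls Gk. The labels call every sample a preadipocyte sample. They do not say how the knockdown or knockout was made, or whether the 4 samples of a group came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical. The slide identifiers and scan days in the file headers placed the arrays on 8 slides of 4 arrays, scanned on 4 days. Each of the 4 experiments took 1 day and a pair of slides, and each slide held both of its groups. Room temperature and cold therefore differed in slide and scan day as well.

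Intensities were log2-transformed and the 75th percentile of each array was subtracted. Of 44397 spots per array, 1377 control spots were left out. Between 101 and 247 spots per array that Feature Extraction had called outlying were also left out. Spots of the same probe were averaged (399 probes had 10 spots each). The files give RefSeq, Ensembl and other identifiers but the grid names the mm9 build, whereas the reference gene table at hand is for GRCm38.p6, so that table was used for names alone and no coordinates are given. It named 27234 of 39429 probes (69.1%), for 20659 genes. The other 12195 probes stayed outside the comparisons of genes. For each of the 5476 genes with several probes, the probe with the highest mean over all 32 arrays was used. A probe entered a comparison if Feature Extraction called it well above background on at least 4 arrays of the fit. A probe that missed this call on all arrays of a group is described as not well above background there, and its change as at least the fold obtained when each dim signal is raised to the lowest signal called well above background on that array. Where 1 or 2 of a group's 4 arrays had this call, that number is given and the fitted value is not read as a size.

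Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with files read by the data.table package, version 1.17.8), 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The 8 comparisons were each knockdown and knockout against its own control, cold against room temperature in each genotype, the difference of the knockout effect between cold and room temperature, and the difference between the Pparg and Gyk knockdown effects. Pparg, Gk and Ucp1 were also compared with an exact 2-sided permutation test. With 4 against 4 arrays its 70 label orders allow no p under 0.0286, and with 4 against 2 the limit is 0.0667. Beside each count stands the count with the slide as a block. Since the slide holds 1 temperature, the cold comparisons used it as a random block instead. Whether replicate numbers pair the arrays of both groups was checked by correlating their residuals across genes, with a limit of 0.1. Overlaps of calls were tested with a one-sided Fisher exact test, which treats genes as independent although they are not.

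Before the data were examined, 25 gene lists were fixed from textbook knowledge. Those on adipocyte function covered thermogenic and brown adipocyte genes, lipid-droplet, lipid-uptake and adipokine genes, glycerol-phosphate and triglyceride synthesis, lipolysis, de novo lipogenesis, white-adipose-enriched genes, and creatine and calcium cycling. Those on metabolism covered mitochondrial fatty acid oxidation, the peroxisome, the nuclear respiratory chain, the TCA cycle and pyruvate dehydrogenase, branched-chain amino acid breakdown, glucose uptake and glycolysis, and cholesterol synthesis. Those on other cell types covered markers of preadipocytes and fibroblasts, macrophages and inflammation, lymphocytes, endothelium, skeletal muscle, and nerve and Schwann cells. The rest covered the extracellular matrix and its remodelling, the unfolded protein and integrated stress response, proliferation, the interferon response, and immediate-early and handling stress genes. They held 376 entries, 3 of which had no probe. Each list was tested with limma's camera (inter-gene correlation preset at 0.01, adjusted over the lists of a comparison), which compares its members with all other genes. The same test with an estimated correlation, and fry, stand beside it. Members past the threshold were counted after adjustment over all genes, and adjusted over the list alone. Every called list was described. Of the lists without a call but with at least 3 members past the threshold, which the rule takes as well, most were described in the knockdown and knockout comparisons and none in the others.

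The genes to name were set by a rule fixed at the same time. In the 4 knockdown and knockout comparisons it takes Pparg, Gk and Ucp1, then the 6 largest changes in each direction among genes past the threshold whose groups did not overlap and whose probe was well above background on all 4 arrays of the higher group. In the other comparisons it takes the 4 largest in each direction. It adds up to 2 members per described list with the smallest adjusted p. Clone and predicted-gene names were passed over, and some genes that the rule takes are not reported here.

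The procedure was tested on simulated data with changed genes of known size (67, 67 and 66 genes at log2 0.5, 1 and 2). Noise was drawn independently per gene and array, without slide structure, so recovery in the real comparisons may differ. For log2 changes of 0.5, 1 and 2, respectively, it recovered 28.4%, 80.6% and 93.9% in the Pparg knockdown design and 10.4%, 55.2% and 78.8% in the Gyk knockdown design. For the knockout it recovered 34.3%, 73.1% and 92.4% at room temperature and 11.9%, 56.7% and 89.4% in the cold. The number of arrays limits the precision. The 75th percentile of intensity ranged from 588.8 to 806.3 in the Pparg culture groups and from 277 to 603.7 in the mouse groups. In the Gyk culture controls it was 355.5 to 418.1, and in the Gyk knockdown 141.3 to 424.4, with replicates 3 and 4 lowest (141.3 and 245.5). Between 46.71% and 60.87% of spots were well above background, and no spot was saturated.

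The alternatives fixed beforehand were normexp background correction, quantile normalization, no filter or a filter requiring detection on all arrays, the mean of a gene's probes, a replicate block, 1 fit over 16 arrays, array weights, the slide block, an absolute log2 change of at least 1, and leaving out each array in turn. The normexp alternative used median spot intensities with an offset of 50, since the files hold no mean spot intensity. Further alternatives, chosen after seeing the data, left out arrays with low signal or skeletal muscle transcripts and averaged the arrays of a slide. What the control samples were treated with is not given in the sources used here, and proteins and lipids were not analysed here.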

Results

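Transcript levels were measured in 32 mouse samples, 4 per group, from cells in culture and from mice. Pparg encodes the nuclear receptor that drives adipocyte differentiation, and Gk encodes glycerol kinase, which phosphorylates glycerol. The series title names as its subject the control of brown adipocyte inducibility by Pparg, by way of glycerol kinase. The 75th percentile of intensity ranged from 141.3 to 806.3 between arrays. The Pparg knockdown, the Gyk knockdown, and the Pparg knockout at room temperature and in the cold each had their own control arrays, scanned with them on the same slides. Between 12217 and 14066 genes were tested per comparison. All changes below are log2 differences with the standard error of the limma fit, 4 arrays per group, unless stated otherwise.

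In cultured cells, Pparg knockdown lowered its own transcript, glycerol kinase and the uncoupling protein of brown fat together. Pparg signal was 4.24 ± 0.157 (SD, n = 4) in the knockdown and 6.15 ± 0.197 (SD, n = 4) in the control, relative to each array's 75th percentile, a 3.76-fold fall (log2 −1.91, SE 0.12, adjusted p = 8.84e-06). Gk fell 2.72-fold (log2 −1.44, SE 0.10, adjusted p = 1.78e-05) and Ucp1 fell 7.15-fold (log2 −2.84, SE 0.11, adjusted p = 8.06e-07). The exact permutation test of Pparg gave p = 0.0286, the smallest that 4 against 4 arrays allow.

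**Figure D1:**
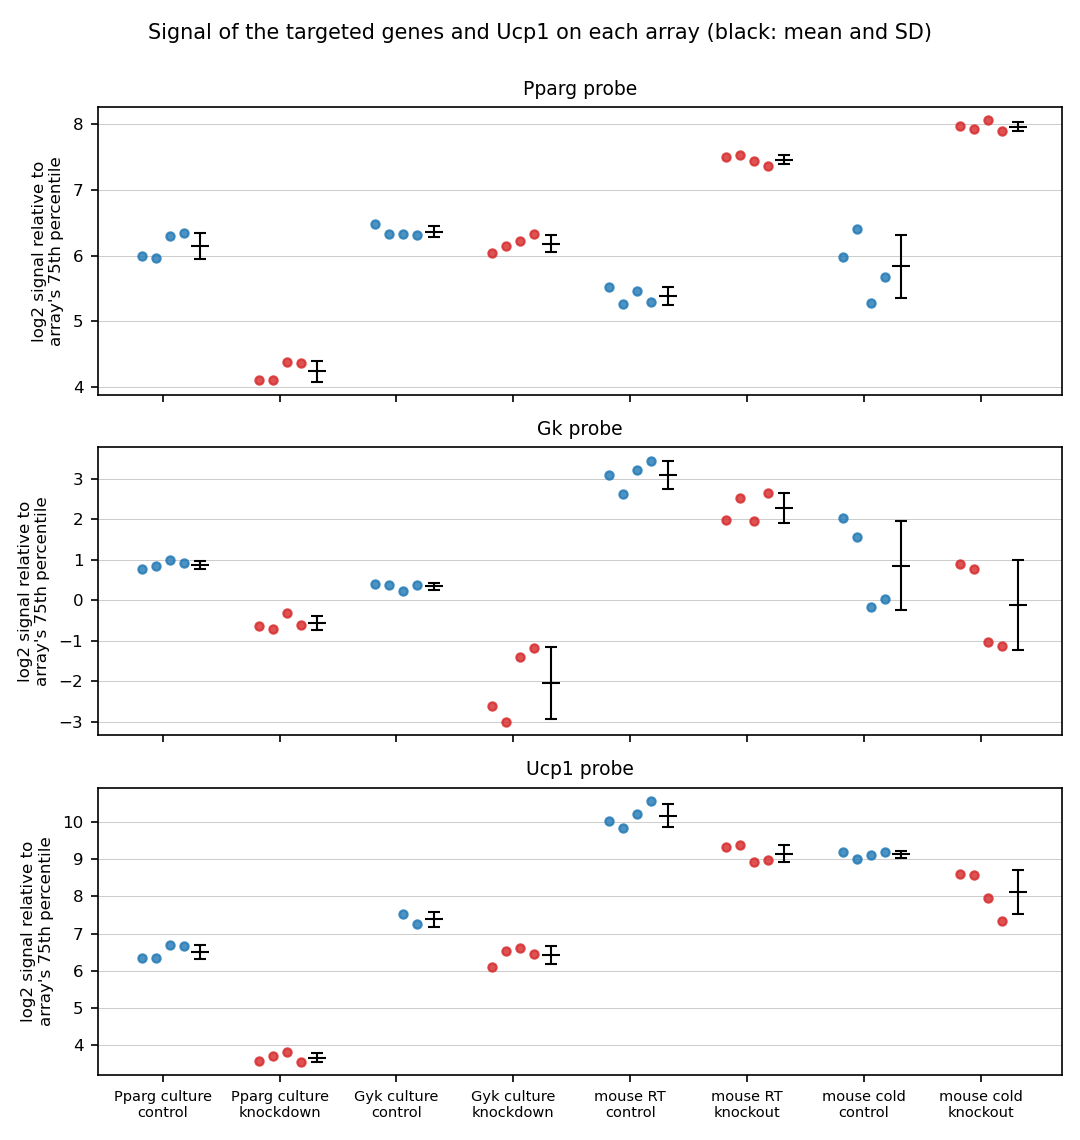
Signal of the single Pparg, Gk and Ucp1 probes on each array, as log2 relative to the array's 75th percentile, with control arrays in blue, knockdown or knockout arrays in red, and the group's mean and SD in black. Pparg was lower than its control in the Pparg knockdown (4.24 against 6.15) and higher in the arrays labelled knockout, at room temperature (7.46 against 5.39) and in the cold (7.96 against 5.83). Ucp1 spots of 2 Gyk control arrays were called outlying by the scanner software and have no point.

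Large falls in the Pparg knockdown were in Tmem45b (27.6-fold lower, log2 −4.79, SE 0.09), Pck1, which makes phosphoenolpyruvate and feeds glyceroneogenesis (12.8-fold lower, log2 −3.68, SE 0.12), the GABA transporter Slc6a13 (12.4-fold lower, log2 −3.63, SE 0.14, with 3 of 4 knockdown arrays well above background) and the glycogen synthase Gys2 (11.8-fold lower, log2 −3.57, SE 0.07). Tex19.1 and Serpinb9f, well above background in all controls, were not well above background in the knockdown and fell at least 11.8-fold and 5.87-fold. Large rises were in Ccdc13 (at least 19.3-fold, adjusted p = 5.88e-06), the acute-phase gene Saa2 (at least 6.32-fold), the semaphorin receptor Plxnb1 (at least 5.99-fold), the matrix metalloprotease Mmp11 (17.6-fold) and the cathelicidin Camp (17.1-fold). Gdpd2 rose too, with 2 of 4 control arrays well above background. Mmp11, Camp and Gys2 each have another probe, which gave log2 changes of 4.02, 4.09 and −3.15.

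Adipocyte genes fell as groups in the Pparg knockdown. Of 15 thermogenic and brown adipocyte genes, 12 fell and 1 rose (also 12 and 1 adjusted over the list alone; median log2 −1.31, camera adjusted p = 8.51e-08), among them Ucp1 and the proton channel Otop1 (log2 −3.24, SE 0.15). Of 22 lipid-droplet, lipid-uptake and adipokine genes, 18 fell and none rose (19 fell adjusted over the list alone; median −1.16, adjusted p = 1.22e-11), including the lipid-droplet protein Plin5 (log2 −2.44) and the acyl-CoA synthetase Acsl1 (log2 −1.75). Of 18 glycerol-phosphate and triglyceride synthesis genes, 15 fell (15 fell and 1 rose adjusted over the list alone; median −1.35, adjusted p = 2.49e-10), with Pck1 and Gpat3 (log2 −1.82) foremost. Of 16 lipolysis genes, 12 fell and 1 rose (13 and 1 adjusted over the list alone; median −1.15, adjusted p = 2.82e-08), and the monoglyceride lipase Mgll fell by 1.98. With an estimated correlation these lists gave adjusted p = 0.137, 0.132, 0.0834 and 0.0834, respectively. De novo lipogenesis genes fell as well (12 of 15, 13 adjusted over the list alone; median −0.833, adjusted p = 5.68e-07, and adjusted p = 0.151 with an estimated correlation). The fatty acid synthase Fasn fell by 1.63 and Acss2 by 1.09. White-adipose-enriched genes were called down by a small margin (3 of 9 fell and 1 rose by either adjustment; median −0.181, adjusted p = 0.0417, and adjusted p = 0.0804 with a slide block and 0.353 with an estimated correlation, over all alternatives 0.0229 to 0.353). Nnat fell by 2.95 and the leptin gene Lep by 1.81.

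Mitochondrial and peroxisomal genes fell too. Fatty acid oxidation had 19 of 20 members lower (19 adjusted over the list alone; median −1.14, adjusted p = 8.05e-12), including Acot2, with 1 of 4 knockdown arrays well above background, and the pyruvate dehydrogenase kinase Pdk4 (log2 −1.44, SE 0.08). In the TCA cycle and pyruvate dehydrogenase list 15 of 16 fell (15 adjusted over the list alone; median −0.809, adjusted p = 3.88e-09), with the succinate-CoA ligase genes Sucla2 and Suclg1 at log2 −1.14 and −1.08. Respiratory chain genes fell in 13 of 21 cases (14 adjusted over the list alone; median −0.56, adjusted p = 4.82e-06), and cytochrome c, Cycs, fell by 0.98. With an estimated correlation the 3 lists gave adjusted p = 0.0919, 0.0905 and 0.0834. Peroxisome genes fell in 14 of 18 cases by either adjustment, all genes or adjusted over the list alone (median −0.732, adjusted p = 6.06e-08, and adjusted p = 0.151 with an estimated correlation), among them the peroxisomal transporter Abcd3 (log2 −0.82) and Hsd17b4 (log2 −0.73). Branched-chain amino acid breakdown genes fell in 7 of 15 cases, also adjusted over the list alone (median −0.522, adjusted p = 0.001, and adjusted p = 0.132 with an estimated correlation). Bckdhb fell by 1.19. Glycolysis genes fell in 8 of 17 cases and 1 rose (10 and 1 adjusted over the list alone; median −0.355, adjusted p = 0.00262, and adjusted p = 0.436 with an estimated correlation). The hexokinase Hk2 fell by 1.13, and the glucose transporter Slc2a1 rose by 0.74.

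Lists of preadipocyte and fibroblast, extracellular matrix, interferon response, macrophage and inflammation, and endothelial genes rose in the same arrays. Whether cells of these types were present in the cultures was not tested. Preadipocyte and fibroblast markers rose in 7 of 13 cases, also adjusted over the list alone (median 0.532, adjusted p = 0.000135, and adjusted p = 0.0834 with an estimated correlation), including the receptor Pdgfrb (log2 1.48, SE 0.07) and Ly6a (log2 1.08, SE 0.09). Extracellular matrix genes rose in 8 of 17 cases, also adjusted over the list alone (median 0.429, adjusted p = 0.000243, and adjusted p = 0.132 with an estimated correlation), led by the collagen cross-linking enzyme Lox (log2 1.96) and the gelatinase Mmp2 (log2 1.86). Interferon response genes rose in 9 of 11 cases (9 rose and 1 fell adjusted over the list alone; median 0.709, adjusted p = 0.00141, and adjusted p = 0.199 with an estimated correlation), such as Ifit3 (log2 1.57) and Ifit1 (log2 1.28). Macrophage and inflammation genes rose in 4 of 9 cases and 1 fell (6 and 1 adjusted over the list alone; median 0.585, adjusted p = 0.0143, and adjusted p = 0.151 with an estimated correlation). The cytokine Il6 rose by 2.38 and Gpnmb by 1.56. Endothelial markers rose in 3 of 6 cases (4 adjusted over the list alone; median 0.429, adjusted p = 0.00615, and adjusted p = 0.132 with an estimated correlation). Flt1 rose by 1.21. Muscle markers were not called (median −0.188, adjusted p = 0.253), although Myl1 fell by 2.42 and the skeletal actin gene Acta1 by 1.60. The other lists without a call were cholesterol synthesis (1 rose and 6 of 18 fell, adjusted p = 0.33), creatine and calcium cycling (3 of 6 rose, adjusted p = 0.291), lymphocyte markers (1 of 3 rose, adjusted p = 0.28), nerve and Schwann cell markers (2 of 8 rose and 1 fell, adjusted p = 0.404), the unfolded protein and integrated stress response (3 of 14 rose and 5 fell, adjusted p = 0.724), proliferation (1 of 13 fell, adjusted p = 0.995) and immediate-early genes (2 of 8 rose and 1 fell, adjusted p = 0.542).

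In this comparison 2323 of 12843 genes rose and 2052 fell, 4375 together, of which 992 changed at least 2-fold. Both slides gave the same direction for all 4375, which is nearly fixed in advance, since these genes were called from the same arrays. Over all genes the changes on the slides correlated at 0.931. Replicate numbers paired the arrays by the residual check (correlations 0.703 to 0.767), but the other number on the same slide did as well (0.69 to 0.725), so slide and pairing cannot be separated. The fit with a replicate block called 7410 genes, 4368 of them among the 4375, and that with a slide block 7596. Camera called 17 lists, fry called 21, and with an estimated correlation camera called 0 (8 at an unadjusted p under 0.05). With the arrays of a slide averaged, a choice made after seeing the data, 996 genes passed.

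Gyk knockdown lowered glycerol kinase itself. Gk fell 5.26-fold (log2 −2.40, SE 0.39, adjusted p = 0.0118), by 3.19 on one slide and by 1.60 on the other. With a replicate block its adjusted p was 0.053. Ucp1 fell 1.94-fold (log2 −0.96, SE 0.20, adjusted p = 0.0375) with 4 knockdown and 2 control arrays, and it missed the threshold under 9 of 16 alternatives, such as a slide block (adjusted p = 0.0713, over all alternatives 0.00242 to 0.143). Both control arrays lay on the slide of knockdown arrays 3 and 4, where the difference was −0.845. The exact permutation test of Ucp1 gave p = 0.0667, the smallest that 4 against 2 arrays allow. Pparg differed by −0.18 (SE 0.11, adjusted p = 0.319; exact permutation p = 0.114). Large falls besides Gk were in Tab2, an adaptor of inflammatory kinase signalling (6.76-fold lower, log2 −2.76, SE 0.45), Denr (log2 −2.44, SE 0.62) and Plagl1 (log2 −2.12, SE 0.22). Elovl3, which elongates very long fatty acids in brown fat, and Olig1 were not well above background in the knockdown and fell at least 2.5-fold and 1.52-fold. Other probes gave −0.825 for Denr and −2.05 to −0.042 for Plagl1. Large rises were in Plcd4 (at least 7-fold), Robo3 (at least 5.63-fold), Mab21l3 (log2 2.46, SE 0.17) and the protease St14 (at least 4-fold). Inka2 and the alpha-globin gene Hba-a2, a transcript of red blood cells, rose too, each with 1 of 4 control arrays well above background.

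Thermogenic and brown adipocyte genes fell in 7 of 16 cases in the Gyk knockdown (10 adjusted over the list alone; median −0.707, adjusted p = 2.32e-06, and adjusted p = 0.0611 with an estimated correlation), including Elovl3 and the cytochrome c oxidase subunit Cox8b (log2 −1.04). Gk belongs to this list too and counts among its falling genes, a fall that the knockdown itself set. The list was not tested without Gk. A pair of lists kept their calls with an estimated correlation, each with adjusted p = 0.0395. These were fatty acid oxidation (5 of 20 fell, 10 adjusted over the list alone; median −0.348, adjusted p = 5.23e-05), where Acadl fell by 1.36 and Pdk4 by 0.85, and the TCA cycle (3 of 16 fell by either adjustment, also adjusted over the list alone; median −0.574, adjusted p = 7.92e-05), where Idh3a fell by 1.14 and Sucla2 by 0.78. Glycerol-phosphate and triglyceride synthesis genes fell in 3 of 18 cases (9 adjusted over the list alone; median −0.404, adjusted p = 0.00145, and adjusted p = 0.0611 with an estimated correlation), among them Gk itself and the acyltransferase Agpat2 (log2 −1.10). Lipid-droplet genes fell in 4 of 22 cases (5 adjusted over the list alone; median −0.212, adjusted p = 0.00145, and adjusted p = 0.111 with an estimated correlation), among them Acsl1 (−0.63) and Plin5 (−0.55). Branched-chain amino acid breakdown fell in 2 of 15 cases (4 adjusted over the list alone; median −0.283, adjusted p = 0.00546). Aldh6a1 fell by 1.03 and Auh by 0.64. Respiratory chain genes fell in 2 of 21 cases (5 adjusted over the list alone; median −0.195, adjusted p = 0.0096). Sdha fell by 0.59 and Uqcrc2 by 0.45. Cholesterol synthesis genes fell in 2 of 18 cases by either adjustment, also adjusted over the list alone (median −0.25, adjusted p = 0.0281), namely Insig1 (−1.20) and Idi1 (−0.66). These 3 lists had adjusted p = 0.111 with an estimated correlation.

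Peroxisome genes were called down in the Gyk knockdown (3 of 17 fell, 4 adjusted over the list alone; median −0.39, adjusted p = 0.0324, and adjusted p = 0.168 with an estimated correlation), with Ech1 at −0.73 and Ehhadh at −0.65, but the list's median was −0.284 on one slide and 0.0272 on the other. Extracellular matrix genes rose in 6 of 17 cases, also adjusted over the list alone (median 0.233, adjusted p = 0.0421, and adjusted p = 0.306 with an estimated correlation), such as Tagln (1.20) and Col5a1 (0.57). Of 12 interferon response genes, Ifih1 (1.52, SE 0.35) passed, also adjusted over the list alone, while the list's median was 1.18 (adjusted p = 0.00353, and adjusted p = 0.347 with an estimated correlation). Lists without a call included lipolysis (1 of 16 fell, 3 adjusted over the list alone; adjusted p = 0.0643), de novo lipogenesis (3 of 15 fell, with Scd2 at −0.80 and Thrsp at −0.51; adjusted p = 0.147) and the stress response (3 of 14 rose, with Sesn2 at 0.86 and Sdf2l1 at 0.84, and 2 fell; adjusted p = 0.3).

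The Gyk comparison gave 568 higher and 502 lower genes of 12217, 1070 together (1347 with a slide block), 248 of them changed at least 2-fold. The count was 399, 333, 298 and 347 without control arrays 1 to 4, respectively, 627 without knockdown array 4, and 105 with a replicate block. In the residual check 2 of 4 replicate pairs lay just over the limit of 0.1 (0.0536 to 0.116), so pairing stays open. Other numbers on the same slide gave 0.0329 to 0.0977. Over all genes the changes on the slides correlated at 0.339. Knockdown arrays 3 and 4 had the lowest signal of the series. Without them, chosen after seeing the data, 1322 genes passed, and without their slide, which left 2 arrays against 2, limma called 0 genes (2261 at an unadjusted p under 0.05). Gk was then at −3.19 (adjusted p = 0.0648, over all alternatives 0.000117 to 0.0648).

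Pparg knockdown and Gyk knockdown moved many genes alike. Among 12057 genes tested in both, 268 rose in both against 97.8 expected by chance (Fisher exact p = 4e-65) and 243 fell in both against 82.4 (Fisher exact p = 7.62e-66), while 82 of the 593 genes called in both went opposite ways. The shared rising genes numbered 96 without Gyk control array 3 (125, 97 and 118 without controls 1, 2 and 4, and 151 without Gyk knockdown array 4), and the shared falling genes 70 (90, 84 and 77 without controls 1, 2 and 4). With a replicate block as a term for pairing they numbered 43 and 29. Of the genes that fell in the Pparg knockdown, 2016 were measured in the Gyk experiment and 74.3% were lower there (median −0.23, camera p = 7.92e-15, p = 0.00281 with an estimated correlation). Those that rose had a median of 0.218 (camera p = 7.31e-09, p = 0.0398 with an estimated correlation). The correlation of the changes across genes was 0.31, where genes are not independent replicates.

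The Pparg knockdown effect lay far below the Gyk knockdown effect in Tmem45b (difference −4.17, adjusted p = 1.7e-10), the adenylyl cyclase Adcy5 (−4.13), Krt36 (−3.94) and Colq (−3.89), and far above it in Mmp11 (4.92), Lrrc75b (4.54, with 3 of 4 Gyk knockdown arrays well above background) and Mlana (4.33). Ccdc13 was well above background on the 4 Pparg knockdown arrays and on no other culture array, so the size of its difference was not measured. The lipid groups fell further with Pparg knockdown. The lists lower in this difference with an estimated correlation as well were lipid-droplet genes (13 of 22 lower, 15 adjusted over the list alone; median −0.771, adjusted p = 1.13e-08, and adjusted p = 0.0427 with an estimated correlation), glycerol-phosphate and triglyceride synthesis (6 of 18, 10 adjusted over the list alone; median −0.689, adjusted p = 2.32e-05, and adjusted p = 0.0222 with an estimated correlation) and lipolysis (10 of 16 by either adjustment, also adjusted over the list alone; median −0.855, adjusted p = 2.94e-07, and adjusted p = 0.00501 with an estimated correlation). Preadipocyte and fibroblast markers were higher (7 of 13, 10 adjusted over the list alone; median 1.01, adjusted p = 3.86e-06, and adjusted p = 0.011 with an estimated correlation). Examples were Pck1 (−2.62), Mgll (−2.21), Plin5 (−1.89), Ucp1 (−1.88), Fap (2.71, with 3 of 4 Pparg controls well above background) and Pdgfra (1.15). Thermogenic genes (median −0.63, adjusted p = 0.00311), fatty acid oxidation (−0.681, adjusted p = 2.07e-06), peroxisome (−0.405, adjusted p = 0.00192), de novo lipogenesis (−0.764, adjusted p = 0.000304) and respiratory chain genes (−0.301, adjusted p = 0.0256) were called down, with adjusted p = 0.217, 0.0594, 0.248, 0.16 and 0.217 with an estimated correlation. Of the 21 respiratory chain genes 0 passed by themselves. TCA cycle genes were not called (0 of 16 passed, median −0.195, adjusted p = 0.0821, and adjusted p = 0.217 with an estimated correlation). The difference passed for 1631 of 13117 genes, 825 upward and 806 downward (2999 with a slide block).

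In mice at room temperature, the arrays labelled knockout had less Ucp1 and Gk than controls and more signal at the Pparg probe. Ucp1 fell 2.02-fold (log2 −1.02, SE 0.18, adjusted p = 0.00213) and Gk fell 1.77-fold (log2 −0.82, SE 0.22, adjusted p = 0.017; exact permutation p = 0.0571). Gk did not pass in 1 fit over the 16 mouse arrays (adjusted p = 0.25, over all alternatives 0.00737 to 0.25). Pparg signal was 7.46 ± 0.0712 (SD, n = 4) against 5.39 ± 0.13 (SD, n = 4) in controls, 4.22-fold higher (log2 2.08, SE 0.09, adjusted p = 4.42e-06). The array carries 1 Pparg probe, and where it lies relative to the deleted part is not known here, so its signal is no measure of the deletion. Large falls were in the glycosyltransferase B4galnt2 (at least 18.7-fold), Fam131c (at least 18.5-fold), the kinase Sgk2 (39.6-fold, log2 −5.31), Amn (at least 9.09-fold), Cpne5 (28.2-fold, log2 −4.82) and Elovl3 (27.7-fold, log2 −4.79). Large rises were in the gluconeogenic enzyme Fbp1 (126-fold, log2 6.98, SE 0.28), myoglobin, Mb (98.9-fold, log2 6.63, SE 0.72), Cyp4f14 (at least 39-fold), the acute-phase gene Saa3 (at least 20.6-fold), the prostaglandin synthase Ptgs1 (66.9-fold, log2 6.06, SE 0.12) and Cyp2f2 (52.3-fold, log2 5.71, SE 0.58). Mb belongs to the muscle markers, whose mean signal was 1.27 on knockout array 1 and −3.69 to −3.32 on the other 3, but Mb itself was 6.19 to 7.04 on the 4 knockout arrays and −1.47 to 2.08 on the controls.

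Of 18 thermogenic genes at room temperature, 11 fell and 2 rose (11 and 3 adjusted over the list alone; median −0.85, adjusted p = 0.00909), with Elovl3 and Otop1 (log2 −4.10, SE 0.10) lowest. Peroxisome genes fell in 13 of 19 cases and 5 rose, also adjusted over the list alone (median −0.912, adjusted p = 0.0192). The import factor Pex14 fell by 1.65 and Pex16 by 1.54. Glycerol-phosphate and triglyceride synthesis genes fell in 11 of 17 cases and 3 rose (11 and 4 adjusted over the list alone; median −0.82, adjusted p = 0.0246). The glycerol-phosphate dehydrogenase Gpd1 fell by 1.69. Lipolysis genes fell in 9 of 16 cases (10 adjusted over the list alone; median −0.627, adjusted p = 0.00899). Prkar2b fell by 1.38 and the fatty acid binding protein Fabp4 by 1.10. Fatty acid oxidation genes fell in 14 of 20 cases and 1 rose, also adjusted over the list alone (median −0.43, adjusted p = 0.00899). The carnitine carrier Slc25a20 fell by 1.34. TCA cycle genes fell in 11 of 16 cases (11 fell and 1 rose adjusted over the list alone; median −0.362, adjusted p = 0.00909). Suclg1 fell by 1.31 and citrate synthase, Cs, by 1.13. Endothelial markers fell in 9 of 12 cases, also adjusted over the list alone (median −0.55, adjusted p = 0.00909), including Gpihbp1 (−1.06) and the endothelial cadherin Cdh5 (−0.64). Each of these 7 lists had adjusted p = 0.796 with an estimated correlation.

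Cholesterol synthesis genes were the group that rose at room temperature (8 of 18, 9 adjusted over the list alone; median 0.555, adjusted p = 0.0246, and adjusted p = 0.892 with an estimated correlation). Idi1 rose by 1.46. Their median was 0.125 on one slide and 0.947 on the other. Groups without a call but with several members past the threshold included lipid-droplet genes (6 rose and 12 of 22 fell, with the glycerol channel Aqp7 at −1.95 and Hilpda at 1.54; adjusted p = 0.153), respiratory chain genes (3 rose and 13 of 21 fell, with Cycs at −0.89 and Atp5g1 at 2.54; adjusted p = 0.0518, but 0.024 with a slide block), glycolysis (2 rose and 8 of 17 fell, with Ldha at −1.08; adjusted p = 0.275), branched-chain amino acid breakdown (5 rose and 4 of 16 fell, with Mccc1 at 1.83 and Bckdhb at −1.82; adjusted p = 0.682), creatine and calcium cycling (3 rose and 3 of 7 fell, with Slc6a8 at 1.24 and Alpl at −2.50; adjusted p = 0.827) and nerve and Schwann cell markers (5 of 7 rose; adjusted p = 0.0518). Preadipocyte markers (3 rose and 1 of 15 fell, with Vim at 1.70; adjusted p = 0.815), the stress response (3 rose and 2 of 14 fell, with Sesn2 at 1.64 and Xbp1 at 1.37; adjusted p = 0.534) and proliferation genes (1 rose and 2 of 10 fell, with Cenpa at −1.67; adjusted p = 0.534) were not called either.

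At room temperature 2590 of 13230 genes rose and 3313 fell, 5903 together (6060 with a slide block), and 1311 changed at least 2-fold. Both slides gave the same direction for all 5903, which were called from the same arrays. Over all genes the changes on the slides correlated at 0.806. Higher genes made up 43.9% of the 5903, against 52.2% of 5867 with quantile normalization and 30.6% of 7746 with no filter on dim probes, so the prevailing direction depended on the processing. The 75th percentile of intensity was 498.5 to 603.7 on the knockout arrays and 292.7 to 406.2 on their controls. Camera called 8 lists (9 with a slide block), fry called 9, and with an estimated correlation camera called 0 (0 at an unadjusted p under 0.05). Of the genes that fell in the Pparg knockdown, 74.3% of 1962 were lower in the knockout at room temperature (median −0.368, camera p = 4.66e-12, p = 0.0165 with an estimated correlation), and those that rose had a median of 0.171 (camera p = 2.04e-07, p = 0.0343 with an estimated correlation). Among 11923 shared genes, 1011 fell in both against 507 expected (Fisher exact p = 4.28e-160) and 655 rose in both against 403 (Fisher exact p = 5.03e-49), while 427 of 2093 went opposite ways.

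In the cold, the arrays labelled knockout again had less Ucp1 (2.02-fold lower, log2 −1.01, SE 0.27, adjusted p = 0.0199). The Ucp1 call was lost without knockout array 3 (adjusted p = 0.0522) and without the 3 arrays richest in muscle transcripts (log2 −0.78, adjusted p = 0.0664, over all alternatives 0.004 to 0.0664). Within the slides Ucp1 differed by −0.514 and −1.51. Gk was 0.98 lower on the log2 scale in value, and the difference did not pass (SE 0.65, adjusted p = 0.279; exact permutation p = 0.257). Its difference was 0.284 without those 3 arrays, which leaves controls of 1 slide against knockout arrays of both, whereas within the slides it was −0.955 and −1.01. Over all alternatives its adjusted p ranged from 0.00102, with a slide block, to 0.758. The Pparg probe was 4.37-fold higher (7.96 ± 0.0705 against 5.83 ± 0.479, SD, n = 4; log2 2.13, SE 0.22, adjusted p = 0.000401). Large rises were in Clic6 (at least 29.8-fold), Cyp2f2 (101-fold), Anxa8 (90.3-fold), Nrip2 (71.8-fold) and clusterin, Clu (64.8-fold, log2 6.02, SE 0.16). The estrogen sulfotransferase gene Sult1e1 rose too, with 1 of 4 control arrays well above background. Large falls were in the muscle ankyrin Ankrd2 (at least 6.77-fold), Otop1 (16.8-fold, log2 −4.07), Clstn3 (13.8-fold, log2 −3.79) and Flrt1 (13.6-fold, log2 −3.77). Elovl3 and the urate transporter gene Slc22a12 fell too, each with 2 of 4 knockout arrays well above background.

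Fatty acid oxidation genes fell in 16 of 20 cases in the cold and 1 rose (17 and 1 adjusted over the list alone; median −0.939, adjusted p = 3.7e-06). Acads fell by 1.40 and Hadh by 0.94. TCA cycle genes fell in 13 of 16 cases, also adjusted over the list alone (median −0.884, adjusted p = 4.71e-06). Suclg1 fell by 1.25 and Cs by 1.03. Peroxisome genes fell in 12 of 18 cases (16 adjusted over the list alone; median −0.819, adjusted p = 2.34e-05). Pex5 fell by 1.32 and Scp2 by 1.24. Respiratory chain genes fell in 11 of 21 cases (13 fell and 1 rose adjusted over the list alone; median −0.46, adjusted p = 9.98e-05). Cycs fell by 1.22 and Sdhd by 0.81. With an estimated correlation these lists gave adjusted p = 0.327, 0.315, 0.315 and 0.338. Cholesterol synthesis genes fell in 13 of 17 cases (16 adjusted over the list alone; median −1.16, adjusted p = 3.07e-05, and adjusted p = 0.338 with an estimated correlation). The lanosterol synthase Lss fell by 1.79 and Hmgcs1 by 1.08. Branched-chain amino acid breakdown fell in 7 of 15 cases and 1 rose (8 and 1 adjusted over the list alone; median −0.445, adjusted p = 0.0108, and adjusted p = 0.338 with an estimated correlation). This call was lost without the 3 arrays richest in muscle transcripts (median −0.393, adjusted p = 0.0643). Bckdhb fell by 1.10 and Mccc2 by 0.64.

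Lipid genes of the adipocyte fell in the cold as well. Lipolysis genes fell in 10 of 16 cases (11 adjusted over the list alone; median −0.799, adjusted p = 0.000375). The hormone-sensitive lipase Lipe fell by 2.24 and Prkar2b by 1.16. De novo lipogenesis genes fell in 7 of 15 cases (8 adjusted over the list alone; median −0.887, adjusted p = 0.000654, and −1.52 without the 3 arrays richest in muscle transcripts). The desaturase Scd1 fell by 1.97 and Fasn by 1.94. Glycerol-phosphate and triglyceride synthesis genes fell in 9 of 17 cases and 1 rose, also adjusted over the list alone (median −0.725, adjusted p = 0.000664). Aqp7 fell by 1.82 and Mogat2 rose by 2.74. Lipid-droplet genes fell in 12 of 22 cases and 2 rose (13 and 3 adjusted over the list alone; median −0.752, adjusted p = 0.00204). The droplet fusion protein Cidec fell by 2.24. Thermogenic genes fell in 8 of 17 cases and 1 rose, also adjusted over the list alone (median −0.941, adjusted p = 0.0108), with Otop1 and the nuclear receptor Ppara (−2.17) lowest. Their call was lost without those 3 arrays (median −0.357, adjusted p = 0.0643). With an estimated correlation the 5 lists gave adjusted p = 0.251, 0.371, 0.315, 0.251 and 0.338.

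Preadipocyte and fibroblast markers rose in 10 of 15 cases (13 adjusted over the list alone; median 0.66, adjusted p = 1.19e-05, and adjusted p = 0.315 with an estimated correlation). Vimentin, Vim, rose by 1.70 and Gsn by 1.31. Macrophage and inflammation genes rose in 9 of 12 cases (10 adjusted over the list alone; median 1.08, adjusted p = 2.34e-05, and adjusted p = 0.251 with an estimated correlation). Mpeg1 rose by 1.24 and Cd14 by 1.11. Extracellular matrix genes rose in 8 of 15 cases (9 adjusted over the list alone; median 0.633, adjusted p = 0.000489, and adjusted p = 0.301 with an estimated correlation). The collagen gene Col3a1 rose by 1.18 and Col1a1 by 1.05. Interferon response genes rose in 7 of 10 cases, also adjusted over the list alone (median 0.782, adjusted p = 0.000975, and adjusted p = 0.338 with an estimated correlation). Ifit3 rose by 1.78 and Usp18 by 1.15. Creatine and calcium cycling genes rose in 3 of 8 cases, also adjusted over the list alone (median 0.295, adjusted p = 0.0399, and adjusted p = 0.301 with an estimated correlation). Gamt rose by 3.19 and Ckb by 2.78. Of 8 immediate-early genes Jun (1.40) rose, and none passed adjusted over the list alone (median 1.48, by slide 0.742 and 2.04, adjusted p = 0.0445, and adjusted p = 0.469 with an estimated correlation). Without the 3 arrays richest in muscle transcripts their median was −0.04 (adjusted p = 0.48), which leaves controls of 1 slide against knockout arrays of both. Within the slides Fos differed by 2.57 and 3.29 and Jun by 0.823 and 1.98. Fos was at −5.29 and −6.28 on cold controls 1 and 2 but −0.243 and −1.08 on controls 3 and 4, and at −6.44 on knockout array 1 but 0.00156 to 2.83 on the others. Lists without a call included lymphocyte markers (3 of 6 rose, 4 adjusted over the list alone, with Ptprc at 0.96; adjusted p = 0.0968), proliferation genes (2 rose, with Mki67 at 1.35, and 2 of 10 fell; adjusted p = 0.177) and the stress response (3 of 14 fell, with Asns at −0.99; adjusted p = 0.837).

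Skeletal muscle markers moved with some arrays of the cold groups. Their mean signal was 3.76 and 4.23 on control arrays 1 and 2 and 1.44 on knockout array 4, against −3.91 to −1.30 on the other controls and −3.27 to −2.68 on the other knockout arrays, so the list's median was −8.05 on one slide and 1.61 on the other (adjusted p = 0.123 over both). The gene groups and single genes above, among them the muscle gene Ankrd2, were measured on the same arrays. Control array 4 (−1.30) held some muscle transcripts as well, such as Tnnt3 at −1.05 against −4.64 on control 3. In the cold 1774 of 12981 genes rose and 2380 fell, 4154 together (5377 with a slide block), with 1313 changed at least 2-fold. Without the 3 arrays richest in them, chosen after seeing the data, 2161 genes passed and 14 of the 17 called lists kept their call. The 3 arrays are both controls of 1 slide and a knockout array of the other, so the slides were unbalanced without them, and control 4 stayed in. Camera called 17 lists, fry called 19, and with an estimated correlation camera called 0 (3 at an unadjusted p under 0.05). Over all genes the changes on the slides correlated at 0.644. In the residual check 2 of 4 replicate pairs lay over the limit (0.0412 to 0.499), and a replicate block gave 4719 genes.

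The knockout changes at both temperatures overlapped. Among 12401 genes tested in both, 1444 fell in both against 600 expected, and 726 rose in both against 338 (Fisher exact p = 5.14e-122), while 129 of 2299 genes called in both went opposite ways. The correlation of the changes across genes was 0.604. Genes that fell in the Pparg knockdown were lower in the cold knockout in 82.4% of 1978 cases (median −0.536, camera p = 9.13e-23, p = 0.0201 with an estimated correlation), and those that rose had a median of 0.402 (camera p = 1.31e-21, p = 0.00354 with an estimated correlation).

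**Figure D2:**
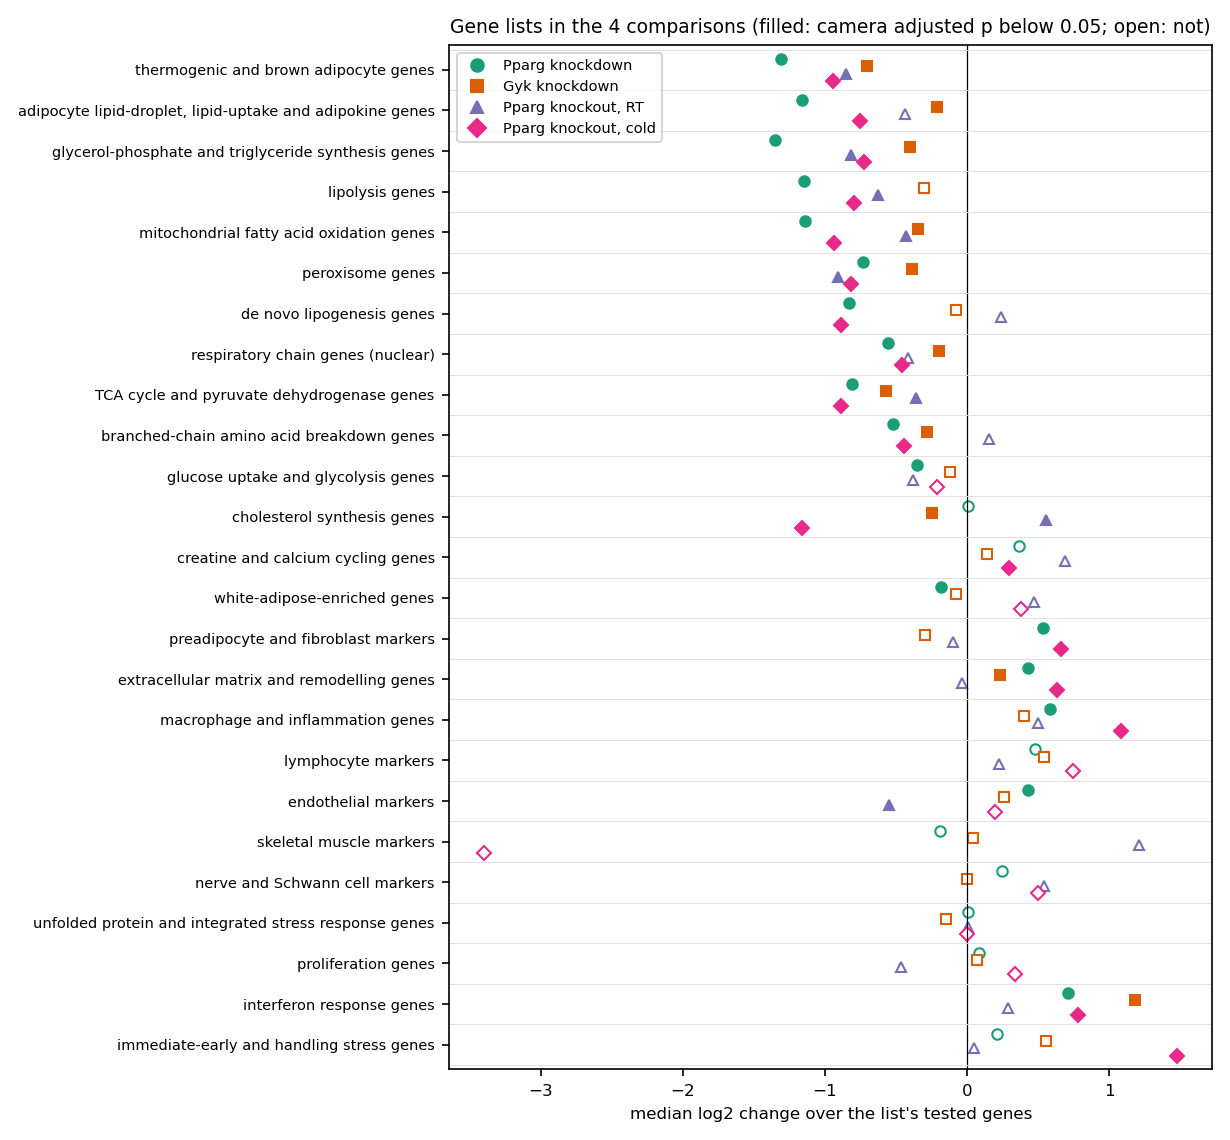
Median log2 change of each of the 25 gene lists over its tested genes in the 4 knockdown and knockout comparisons, with filled marks where camera's adjusted p was below 0.05 and open marks elsewhere. Lipid and mitochondrial lists lie left of 0 in the Pparg knockdown (fatty acid oxidation at −1.14) and in the knockout in the cold (−0.939), and cholesterol synthesis lies at 0.555 at room temperature and −1.16 in the cold.

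The knockout effect itself differed between temperatures. Of 18 cholesterol synthesis genes, 13 were lower in the cold relative to room temperature (15 adjusted over the list alone; median −1.59, adjusted p = 4.49e-10, and adjusted p = 0.302 with an estimated correlation), with Idi1 at −2.36. De novo lipogenesis genes were lower too (5 of 15, 10 adjusted over the list alone; median −1.08, adjusted p = 6.87e-05, and adjusted p = 0.607 with an estimated correlation), with Fasn at −1.97 and Pnpla3 at −1.91. So were fatty acid oxidation (median −0.463, adjusted p = 0.00626; Hadha at −1.42), TCA cycle (−0.324, adjusted p = 0.0148; Idh3b at −0.77) and branched-chain amino acid breakdown genes (−0.512, adjusted p = 0.0148; Mccc1 at −1.06), each with adjusted p = 0.65 with an estimated correlation, and lipid-droplet genes (−0.502, adjusted p = 0.0475, and adjusted p = 0.33 with an estimated correlation; Plin2 at −1.56). Higher in the cold were preadipocyte markers (4 of 15, median 0.768, adjusted p = 6.87e-05, and adjusted p = 0.303 with an estimated correlation; Mfap5 at 1.26). Endothelial markers (5 of 12, 6 adjusted over the list alone, median 0.774, adjusted p = 6.87e-05; Esam at 1.33), extracellular matrix genes (5 rose and 1 of 17 fell, median 0.794, adjusted p = 0.000459; Ccn2 at 1.76) and creatine and calcium cycling genes (median 0.803, adjusted p = 0.0421; Alpl at 2.53) were higher as well, each with adjusted p = 0.302 with an estimated correlation. Muscle markers were called down with none of 14 members past the threshold (median −4.57, adjusted p = 0.0148, and adjusted p = 0.65 with an estimated correlation), on the arrays with muscle transcripts described above. Without the 3 cold arrays richest in them and room-temperature knockout array 1, chosen after seeing the data, 6 of the 11 calls were kept. Of the lists that lost theirs, the medians of the TCA cycle (−0.313, adjusted p = 0.0593), branched-chain amino acid breakdown (−0.512, adjusted p = 0.0593) and lipid-droplet genes (−0.411, adjusted p = 0.123) stayed near their values with all arrays, and fewer arrays were left. Those of fatty acid oxidation (−0.272, adjusted p = 0.211) and muscle markers (−0.355, adjusted p = 0.763) shrank by over 1.5 times.

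Single genes differed in the knockout effect as well. Glod5 (6.16 upward in the cold) and Ptgs1 (−3.36) were well above background on all 16 mouse arrays. Flrt1 (−4.94) was so on all but 1 room-temperature control. Golga7b, which passed downward, was so on all but 2 room-temperature controls, and another probe gave −0.496. Clic6 was well above background on the 4 cold knockout arrays and on no other mouse array, Dynlrb2 on those 4, 1 cold control and 1 room-temperature knockout array, and Sult1e1 on all 8 knockout arrays, 1 cold control and 2 room-temperature controls. These 3 genes passed upward, but the size of their differences was not measured. The difference passed for 1879 of 14066 genes, 860 upward and 1019 downward (2718 with a slide block), and for 1231 without room-temperature knockout array 1. Each knockout array shared its slide with controls, so a slide effect common to both genotypes cancels in this difference.

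Cold against room temperature gave the largest counts, with no slide or scan day in common. In control mice 5575 of 13131 genes were higher and 3202 lower, 8777 together (8008 with slide as a random block), and the median of all genes was shifted by 0.255. In knockout mice 5654 of 13393 were higher and 3392 lower, 9046 together (7994), with a shift of 0.242. Ucp1 fell in the cold in both (log2 −1.04, adjusted p = 0.000433, and −1.03, adjusted p = 0.0101), by 1.29 and 1.28 relative to that shift. Gk fell as well (−2.24, adjusted p = 0.00316, and −2.40, adjusted p = 0.00247), by 2.50 and 2.65 relative to the shift. Its level in the cold differed between slides, with controls at 2.02 and 1.56 on the slide of the muscle-rich control arrays and −0.175 and 0.0323 on the other, against 2.63 to 3.46 at room temperature. Knockouts were at 0.894 and 0.777 on the former and −1.03 and −1.13 on the latter, against 1.96 to 2.66 at room temperature. The differences of the other genes include the shift, and the tests were run without subtracting it. Dbt, the core subunit of branched-chain ketoacid dehydrogenase, was at least 104-fold lower in cold controls and at least 68.5-fold lower in cold knockouts, and Zcrb1 was at least 116-fold lower in cold knockouts. Rpe (at least 51.7-fold) was also lower in cold controls, as were Zcrb1 and Rpl34-ps1, with 1 and 2 of 4 cold controls well above background, while the hormone gene Fgf21 (at least 90.9-fold) and the transcription factor Klf15 (at least 68.3-fold) were lower in cold knockouts. Dbt and Rpe were well above background on the 8 room-temperature arrays and on no cold or culture array. Car12 (at least 16.3-fold), Aqp5 (5.53, with 3 of 4 room-temperature controls well above background) and Lctl (5.28) were higher in cold controls, as was B3galt2, with 1 of 4 room-temperature controls well above background. Higher in cold knockouts were Clic6 (at least 36.7-fold), Dynlrb2, with 1 of 4 room-temperature knockout arrays well above background, and the immediate-early receptor genes Nr4a1 (5.58) and Nr4a3 (at least 11.6-fold).

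In control mice camera called no list for cold (0 of 25, 4 at an unadjusted p under 0.05, fry 13), although at least 3 members of each of the 25 lists passed. In knockout mice it called cholesterol synthesis genes, which were lower (13 of 18 fell and 1 rose, 13 and 2 adjusted over the list alone; median −1.21, adjusted p = 0.000362, and adjusted p = 0.963 with an estimated correlation). Sqle fell by 2.03. Different probes of the same gene gave the same sign in 68.2% of cases in controls and 68.8% in knockouts, against 94.6% in the Pparg knockdown and 93.7% in the cold knockout comparison, so a gene's change between temperatures depends more on its probe. Itgam was −3.95 by the probe used in controls, and −0.137 to 2.25 by its other probes. Temperature and array run cannot be told apart in this design.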

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

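The test for swapped labels and the alternatives that left out arrays were chosen only after the results were seen, and the other tests in this part were written before. The SEs of medians over genes in this part come from resampling genes, not arrays. They treat genes as independent and leave out the spread between samples.

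The Pparg probe gave a higher signal in the arrays labelled knockout than in their controls, at room temperature and in the cold. Swapped control and knockout labels would raise the genes that fell in the Pparg knockdown, whereas their median was −0.368 (bootstrap SE 0.0159) at room temperature and −0.536 (SE 0.0142) in the cold, which argues against a swap. Array scaling alone would bring the difference below 1, and its lowest value over unscaled, normexp and quantile-normalized signal was 1.94 (SE 0.262). The array has 1 Pparg probe, so whether it lies outside the deleted part and reads a transcript that remains cannot be told apart from a rise of the whole transcript. No biological explanation was tested.

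Room-temperature and cold mouse arrays differed at 8777 genes in controls and 9046 in knockouts, with 68 genes well above background on all 8 room-temperature arrays and on none of the other 24. A probe-specific difference between array runs stays open. Where 1 probe differed by over 3, the other's median share of that was 0.848 in knockouts (51 genes, SE 0.048). In controls it was 0.493 (40 genes, SE 0.17). Over 2, shares were 0.715 (210 genes) and 0.627 (188 genes), against 0.882 and 0.914 in the room-temperature and cold knockout. Random rather than oligo-dT priming would raise histone genes on 1 set of arrays by over 2. Their median difference relative to all genes was 0.493 (SE 0.206) in knockouts and 0.421 (SE 0.333) in controls. Both lie below the limit of 1 set beforehand by over their SE, with 28 of 43 histone genes well above background on all 16 mouse arrays, which argues against it. Temperature itself, slide and scan day cannot be told apart.

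The knockout effect on cholesterol synthesis genes was lower in the cold than at room temperature (median difference −1.59). Skeletal muscle RNA on some cold arrays would leave the difference above −0.8 without the 3 arrays richest in it, but it was −1.86 (control 4, with a muscle marker mean of −1.3, stayed in). Array scaling would do so under normexp or quantile normalization, where it was −1.08 and −1.60. A single slide would turn it in some pairing of a cold with a room-temperature slide, but the 4 pairings gave −0.77 and −1.73 with the slide whose controls held most of the muscle RNA, and −1.32 and −2.26 with the other. These values argue against scaling, and against a single slide as the source of the direction. The test of muscle RNA left cold controls of a single slide against cold knockout arrays of both. It therefore mixed slide with genotype and cannot decide on muscle RNA. The direction was the same with the slide whose controls held most of the muscle RNA and with the other. The size varied with the slide pairing, and −0.77 lies above the −0.8 limit of the other tests. Temperature, the array run and muscle RNA stay open as reasons why the effect differed. Clock genes also differed between knockout and control arrays at room temperature, as described below.

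The knockout effect differed between temperatures by a test of the difference for 1879 genes. Single differences were 6.16 for Glod5 and −3.36 for Ptgs1, and −4.94 for Flrt1, with 3 of 4 room-temperature controls well above background. The fitted values of Clic6 (7.03), Dynlrb2 (5.43), Sult1e1 (5.26) and Golga7b (−3.83) are not measured sizes, since 0, 0, 2 and 2 of 4 room-temperature controls and 0, 1, 1 and 4 of 4 cold controls were well above background. Among the gene lists, the median differences were −0.502 for lipid-droplet genes, −0.463 for fatty acid oxidation, −1.08 for de novo lipogenesis, −0.324 for the TCA cycle, −0.512 for branched-chain amino acid breakdown, −1.59 for cholesterol synthesis and −4.57 for skeletal muscle markers. They were 0.803 for creatine and calcium cycling, 0.768 for preadipocyte markers, 0.794 for extracellular matrix genes and 0.774 for endothelial markers. Without the 4 mouse arrays richest in muscle transcripts 5 calls were lost. The medians of lipid-droplet genes (−0.411, adjusted p = 0.123), the TCA cycle (−0.313, adjusted p = 0.0593) and branched-chain amino acid breakdown (−0.512, adjusted p = 0.0593) stayed near their values with all arrays, while those of fatty acid oxidation (−0.272, adjusted p = 0.211) and muscle markers (−0.355, adjusted p = 0.763) shrank.

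Single arrays lay far from the other 3 of their group in 10 of 133 groups tested, and chance gives about 1 in 20. Skeletal muscle markers had a mean of 1.27 on room-temperature knockout array 1 (others −3.694 to −3.324), of 1.442 on cold knockout array 4 (others −3.269 to −2.676), and of −3.78 in a room-temperature control (others −3.577 to −3.562). Of the 14 muscle markers with a probe, 6 were well above background on all cold control arrays and on all room-temperature control arrays, and 0 stood in another list. Among the Gyk culture controls, Pparg was 6.488 on array 1 (others 6.312 to 6.325) and Gk was 0.222 on array 3 (others 0.378 to 0.4023). Plxnb1 was −7.298 in a Pparg culture control and Tab2 was −3.966 in a Gyk knockdown array. Cyp4f14 was −4.528 in a room-temperature control, and Amn (−6.369) and Cpne5 (−0.9654) stood apart in room-temperature knockout arrays.

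The probes without a gene name were outside the comparisons of genes, and some passed the same test. In the Pparg knockdown 433 of 4951 were higher, in the Gyk knockdown 17 of 4418, in the knockout at room temperature 610 of 5220 and in the knockout in the cold 353 of 4631. Lower were 338, 10, 1013 and 364, respectively.

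For each comparison of 4 against 4 arrays, 1 of 35 splits, the real one, gave as many genes, the smallest share that 35 splits allow. The splits treat arrays as exchangeable. In the Pparg culture controls replicates correlated at 0.9981 to 0.9982 within a slide and at 0.9862 to 0.987 between slides. If the 4 samples of a group are technical replicates, these counts do not exclude chance between cultures or animals. The real split of the Pparg knockdown gave 4375 genes and the highest other 2944, which was the split by slide and points to a structure of these samples. In the 8 splits that part all replicate pairs, the highest other was 0. The Gyk knockdown gave 1070 against 4 and the knockout in the cold 4154 against 42, both highest others again being the split by slide. The knockout at room temperature gave 5903 against 1, and cold gave 8777 against 1 in controls and 9046 against 0 in knockouts. For the difference of the knockout effects, 3 of 100 drawn splits gave at least the real 1879, the real one included, and the other 2, up to 2439, kept the real labels of 1 experiment. The highest of those that kept none was 269. The difference of the knockdown effects gave 1631 genes in 1 of 100, and the highest other was 1261. These drawn splits treat arrays as exchangeable too, so chance between cultures or animals is not excluded here either.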

How the results depend on the processing

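Averaging the arrays of a slide and leaving out arrays for low signal or muscle transcripts were chosen only after the data were seen. The medians of the genes from the Pparg knockdown kept their sign and stayed past the threshold in the Gyk knockdown and both knockout comparisons under the alternatives run. Of the values for gene lists under all alternatives, 1420 kept their direction and side of the threshold and 138 lost the call. Of those for named genes, 6631 kept it, 287 lost it, 2 gained it and 6 changed direction. Where no reason is given, the cause was not tested. Signal over background limits dim probes, and 46.71% to 60.87% of spots were well above it.

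With an estimated correlation camera called 0 lists in the Pparg knockdown, 2 in the Gyk knockdown, 0 in either knockout comparison, 0 for cold in knockout mice, 0 for the difference of the knockout effects and 4 for that of the knockdown effects. Unadjusted p under 0.05 held for 8, 8, 0, 3, 0, 4 and 6 lists, respectively, taking the knockout at room temperature before that in the cold, and fry called 21, 17, 9, 19, 8, 6 and 14.

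An absolute log2 change of at least 1 lowered counts by construction, to 992 in the Pparg knockdown, 248 in the Gyk knockdown, 1311 and 1313 in the knockout at room temperature and in the cold, 4367 and 4416 for cold in controls and knockouts, 768 for the difference of the knockout effects and 795 for that of the knockdown effects. Overlaps of rising and falling genes were then 24 and 31 between the knockdowns, 91 and 142 between the Pparg knockdown and the room-temperature knockout, and 227 and 271 between both knockout comparisons.

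Under normexp background correction, Vwf (−0.155) and Ngfr (−0.159) turned in the Pparg knockdown, and Ngfr (−0.228) in the difference of the knockdown effects. Counts fell to 259 in the Gyk knockdown, 2899 in the room-temperature knockout, 5026 for cold in knockout mice, 865 for the difference of the knockdown effects and 610 for that of the knockout effects, where 32.3% were higher against 45.8% before. Overlaps were 77 and 68 between the knockdowns, 337 and 600 between the Pparg knockdown and the room-temperature knockout, and 323 and 930 between both knockout comparisons. Camera called 6 lists for cold in knockout mice and 17 for the difference of the knockout effects. The median of all genes was shifted by 0.182 and 0.289 for cold in controls and knockouts, by 0.12 for the difference of the knockout effects and by −0.137 for that of the knockdown effects, and quantile normalization shifted the cold comparisons by 0.355 and 0.323.

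With no filter on dim probes, which tests more genes, 447 passed in the Gyk knockdown, the knockdowns shared 111 rising and 78 falling genes, and camera called 1 list for cold in controls and 2 in knockouts. With the mean of a gene's probes, Mlxipl turned for cold in controls (−0.434) and knockouts (−0.726), since its probes differ in sign. With 1 fit over 16 arrays the Gyk knockdown gave 2463 genes and shared 460 rising and 431 falling genes with the Pparg knockdown. With the replicate block as a term for pairing, the Pparg knockdown gave 7410 genes and the Gyk knockdown 105, with 43 and 29 shared. With the slide block the Pparg knockdown gave 7596 and the difference of the knockdown effects 2999. The Pparg knockdown then shared 469 and 377 genes with the Gyk knockdown, and 1116 and 1604 with the room-temperature knockout.

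With the arrays of a slide averaged, which leaves fewer samples, the Pparg knockdown gave 996 genes, shared 80 and 99 with the Gyk knockdown and 160 and 240 with the room-temperature knockout. Without the slide of the low-signal Gyk arrays, which leaves 2 against 2, limma called 0 genes (2261 at an unadjusted p under 0.05) and the knockdowns shared 0 and 0, while camera called 11 lists. Without the 3 arrays richest in muscle transcripts the cold knockout gave 2161 genes and shared 398 and 773 with the room-temperature knockout, and Gk in the cold knockout was 0.284 instead of −0.98. This leaves controls of 1 slide against knockout arrays of both slides, and within the slides Gk differed by −0.955 and −1.01. Without these and room-temperature knockout array 1, camera called 6 lists for the difference of the knockout effects.

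Leaving out each array in turn, which leaves fewer samples, gave 298 to 1383 genes in the Gyk knockdown (399, 333, 298 and 347 without controls 1 to 4, and 627 without knockdown array 4). The knockdowns shared 96 to 332 rising genes (125, 97, 96 and 118 without Gyk controls 1 to 4, and 151 without Gyk knockdown array 4) and 70 to 257 falling genes (90, 84, 70 and 77 without these controls). The difference of the knockout effects gave 1231 to 2187 genes (1231 without room-temperature knockout array 1). Camera called 0 to 1 lists for cold in controls (1 without room-temperature control 1) and 1 to 2 in knockouts (2 without cold knockout array 1).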

Other observations

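The genes and the clock test of this part were chosen only after the values were seen.

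Many genes changed alike in the Pparg knockdown in culture and in both knockout comparisons in mice. Among 11598 genes tested in all 3, 325 rose in each against 48.7 expected by chance, and 726 fell in each against 100. Adamtsl2, which encodes a secreted glycoprotein of the extracellular matrix, and Tenm2 rose from signals not well above background on any control array of the 3 comparisons. Cbs, which makes cystathionine from homocysteine, rose by 2.30, 4.24 and 2.84 in the knockdown, the room-temperature knockout and the cold knockout. Lrrc75b rose by 3.68 in the knockdown, and in mice it was well above background on all knockout arrays and on no control array. Clstn3 fell by 3.36, 4.25 and 3.79, the proton channel gene Otop1 by 3.24, 4.10 and 4.07, Tmem45b by 4.79, 3.62 and 3.01, and Pck1 by 3.68, 3.77 and 2.83. The fatty acid receptor gene Ffar4 fell by 2.24, 2.71 and 2.35.

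In the Gyk knockdown, 103 of 720 shared falling genes tested there passed downward and 6 upward, and of 313 shared rising genes 38 passed upward and 10 downward. The rest are not shown to be unchanged. In simulation that design recovered 10.4% of changes of 0.5 and 55.2% of those of 1. The simulated fit had 103 calls against 1070 in the real one, so recovery there may differ. Cbs rose by 1.57 (adjusted p = 0.000576) and Tmem45b fell by 0.616 (adjusted p = 0.0158), while Cyp2f2, which rose in the Pparg comparisons, fell by 1.16 (adjusted p = 0.00653).

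Clock genes differed between room-temperature and cold arrays. Genes that peak with Nr1d1 had a median of 0.802 in controls and 2.30 in knockouts, cold minus room temperature, and genes that peak with Arntl had medians of −0.875 and −1.62. Nr1d1 rose by 3.93 and 4.90 and Dbp by 1.85 and 4.46, but members of the same group went the other way: Hlf fell by 1.28 (adjusted p = 0.0271) and 0.43 (adjusted p = 0.00865), Ciart fell by 2.54 in knockouts (adjusted p = 5.25e-06), and Nr1d2 was at −0.0768 in controls (adjusted p = 0.757). The gap between the medians was 1.68 in controls and 3.91 in knockouts, which is consistent with tissue taken at another time of day, a hypothesis found in the same values. The same gap was −2.19 for the knockout at room temperature and 0.563 in the cold, and 0.253 and −0.377 in the Pparg and Gyk knockdowns. At room temperature 6 of 7 genes of the Nr1d1 group and 3 of 4 of the Arntl group passed. Knockout and control arrays shared slides, scan day and temperature there, so neither temperature nor array run accounts for that gap. Whether time of day or the knockout does was not tested. The gene lists of that comparison and the difference of the knockout effects rest on these arrays. Temperature and array run remain open for the difference between room-temperature and cold arrays.

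On all 24 other arrays but on no room-temperature array, 9 genes were well above background: Comp, Dtx3, Egf, H2ac21, Mfsd13b, Nrn1l, P2rx3, Pola2 and Slc23a3.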
